A study of Mus musculus with 6 samples.

How the data were processed

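RNA was taken from sorted crypt epithelial cells of the small intestine of male mice, 3 wild-type and 3 Apln knockout samples, which the labels call biological replicates. Per the labels' protocols, small intestines were digested with Liberase TL and RNA was extracted with the RNeasy Plus Micro kit. It was amplified with the Ovation Pico WTA System V2, a whole-transcriptome amplification for small amounts of RNA. Libraries were made with the Nextera DNA Flex kit, which fragments and tags DNA with a transposase. STAR 2.6.1 and HTSeq and the genome build mm10 are named in the submitters' processing notes; the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds raw read counts per gene, whole numbers that the authors did not normalize, for 28564 Ensembl gene identifiers in 6 columns, and 0 columns were without a sample. Gene symbols, coordinates, transcript lengths and GC contents came from the GENCODE annotation of the same build, which matched 28543 of the identifiers and left 21 without a symbol. The longest annotated transcript stood for the length of a gene.

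Library totals were 23046880 to 26513481 counts. A few entries took most of them, first of all the mitochondrial ribosomal RNAs: mt-Rnr2 held 42.2%, mt-Rnr1 13.9%, Gm42418 10.0%, CT010467.1 6.92% and Gm23935 2.11% of all counts. The precision for other genes therefore follows from the 5144725 to 7616648 counts per library outside these entries. A count of 0 allows up to 3 counts, or 0.0946 to 0.142 CPM per library; this floor covers counting error only, since reads without molecular identifiers are not independent molecules. Libraries were compared before averaging: the chi-square per degree of freedom between libraries of one group was 6.89 to 27.2 over genes, so none looked like another library counted again.

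Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with the genotype groups (count minimum 10, total minimum 15) left 15122 genes and removed 13442, TMM scaled the libraries, and glmQLFit with glmQLFTest compared knockout with wild type with no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no fold minimum. The common biological coefficient of variation was 0.298. CPM are TMM-scaled, and a prior count of 2 was added for log2 CPM. Gene lists were tested two-sided with camera (limma 3.58.1) in the same design at a preset correlation of 0.01, on every list with at least 5 measured members, with Benjamini-Hochberg adjustment over the 35 lists tested. Of 39 lists of cell types, programmes, other cell types and quality genes with 826 entries, 808 entries matched the table. Single measures per library were compared with two-sided exact permutation tests, for which 3 against 3 allows no p under 0.1. For the number of genes seen at an equal depth, counts outside the 5 most abundant entries were thinned to 5144725 per library, as the mean of 5 draws.

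The comparison, its test, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Named are the apelin genes, the sort markers, 1 or more marker per crypt cell type, the sex check genes Xist and Ddx3y, and up to 4 members of lowest p from each list described. Also named are up to 12 genes per direction of lowest adjusted p under 0.05 whose groups do not overlap and whose symbol is not a predicted, clone-based or pseudogene name; 11 rose and 8 fell by this rule, and 1 that rose is not reported here. Genes named outside the rule are marked as such.

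The test was tried on simulated counts drawn from the real means, library sizes and dispersions with 200 genes changed. Of 14721 genes tested there, it called 6.12% of those changed 1.5-fold, 34.0% at 2-fold, 57.1% at 3-fold and 73.5% at 4-fold, with 4 false calls among 87. On simulated lists camera called the changed list and 0 of 34 unchanged ones. In both trials the simulated counts carried no correlation between genes and no trend with transcript length between the groups. The 4 false calls therefore do not show how often the gene test calls unchanged genes in the real libraries, which had such a trend. Nor can the list trial show how often camera at the preset correlation calls unchanged lists whose genes are correlated. Genes of most real lists were estimated to be correlated. In simulated data with a length trend, the correction for length and GC content brought Spearman's rho between fold change and length from -0.471 to 0.00172.

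Alternatives were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights and a robust quasi-likelihood fit. Others were no filter, a filter of at least 1 CPM in 3 libraries, a fold minimum of 1.5 (glmTreat), the replicate number as a block, leaving out each library in turn, and for lists an estimated correlation and fry. A correction for transcript length and GC content, fitted per library with mgcv 1.9.3 on genes outside every list and entered as an offset, and leaving out the 5 most abundant entries were added after the data had been seen.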

Results

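RNA sequencing was done on epithelial cells from crypts of the mouse small intestine, the pits between the villi that hold the intestinal stem cells, their dividing progeny and the Paneth cells. The cells came from male mice aged 13 weeks and were sorted as live single cells carrying EpCAM, a surface protein of epithelia, and CD44, which is high on crypt cells. Cells with CD31 (endothelium) or CD45 (blood-derived cells) were excluded in the sort. 3 samples were wild type (C57Bl/6) and 3 came from Apln knockout mice. Apln encodes apelin, a secreted peptide whose receptor is encoded by Aplnr, and the comparison asks how the transcriptome of crypt epithelium differs in its absence. The 6 libraries held 23046880 to 26513481 counts each. The 5 most abundant entries, which include both mitochondrial ribosomal RNAs, took most of them. For all other genes 6037237 to 7616648 counts were left per wild-type library and 5144725 to 5623112 per knockout library.

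Apln (ENSMUSG00000037010, X chromosome, 48025146 to 48034853 on the minus strand of mm10) had 29, 7 and 5 counts in wild-type libraries 1, 2 and 3 and 0 counts in each of the 3 knockout libraries. The wild-type mean was 0.516 ± 0.551 CPM (TMM-scaled; SD, n = 3). A floor of 3 counts over the knockout group stands for 0.0468 CPM. Against the pooled wild-type level of 0.477 CPM, Apln was therefore at least 10.2-fold lower in the knockout. Wild-type library 1 held 29 of the 41 counts, and without it the bound was at least 4.22-fold. The gene lay below the count filter and was not tested there; with no filter, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave it an adjusted p of 0.0206. The deleted part of the gene is not given in the sources used here, and counts cover the whole gene. The receptor gene Aplnr had 2 counts over the wild-type libraries and 0 over the knockout libraries, and Apela, the other ligand gene, was not analysed here. The endothelial gene Pecam1 had 33, 7 and 6 counts in wild-type libraries 1, 2 and 3, close to those of Apln. The few Apln reads therefore cannot be assigned to epithelial rather than residual endothelial cells.

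The genes of the positive sort markers differed by less than the SD of the knockout replicates, and for Epcam by more than that of the wild-type replicates. Epcam was at 294 ± 12.9 CPM in wild type and 310 ± 24.6 CPM in knockout, and Cd44 at 57.5 ± 5.61 and 62.2 ± 9.48 CPM (SD, n = 3 each). Among the excluded lineages, Ptprc, which encodes CD45, was at 2.77 ± 0.567 and 1.42 ± 0.335 CPM. The groups did not overlap for Ptprc, but it did not pass edgeR's quasi-likelihood test (unadjusted p = 0.0283, Benjamini-Hochberg adjusted p = 0.264). Pecam1, which encodes CD31, had 46 counts over the wild-type libraries (33, 7 and 6) and 21 over the knockout libraries (13, 1 and 7). The Y-linked gene Ddx3y was at 7.90 ± 2.29 and 9.50 ± 1.57 CPM, and Xist had 24 and 40 counts in all.

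In the knockout crypt cells the nucleolar gene Tcof1 fell with the lowest p of all genes, and single ribosomal protein genes were among those that rose. Rps10 was 2.46-fold, Rps3 1.95-fold and Rpl7a 1.88-fold higher in knockout; all of these encode ribosomal proteins. Rack1, whose protein is a scaffold on the small ribosomal subunit, was 2.14-fold higher, and Eef1g, a subunit of translation elongation factor 1, was 1.80-fold higher. Tcof1, which encodes the nucleolar protein treacle and acts in the transcription of ribosomal RNA genes, was 2.80-fold lower. Irgm2, an interferon-inducible GTPase gene, was 2.64-fold lower.

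Of 15122 genes tested, 26 changed between Apln knockout and wild type, 17 of them higher and 9 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 2297 genes, 1139 higher and 1158 lower. Groups that did not overlap were seen in 20.9% of the tested genes, where chance gives 10%. Tcof1 (chromosome 18, 60813755 to 60848971, minus strand) fell from 32.5 ± 3.36 to 11.6 ± 1.15 CPM, a log2 fold change of -1.49 ± 0.17 (SE) with an adjusted p of 0.0138 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For every other gene named in this paragraph the adjusted p of that edgeR test was 0.0460. Rack1 rose from 209 ± 35.1 to 448 ± 46.4 CPM and Rps3 from 180 ± 21.0 to 352 ± 40.0. Rps10 rose from 56.1 ± 15.4 to 138 ± 16.1, Eef1g from 113 ± 7.96 to 202 ± 16.3 and Rpl7a from 39.0 ± 5.03 to 73.2 ± 8.20. Gpx1, a glutathione peroxidase that removes hydrogen peroxide, rose from 109 ± 8.23 to 210 ± 18.4 CPM, and Cct4, a subunit of the cytosolic chaperonin, from 35.4 ± 3.97 to 67.3 ± 7.06. Others that rose included the lysosomal protease gene Ctsh (11.1 ± 2.17 to 24.5 ± 0.339), the sulfotransferase gene Sult1d1 (9.86 ± 1.57 to 21.4 ± 2.42) and the RNA kinase gene Clp1 (2.90 ± 0.449 to 8.36 ± 1.48). Besides Tcof1, falls were seen for Irgm2 (13.6 ± 1.38 to 5.15 ± 1.39 CPM), the translation initiation factor gene Eif4g3 (36.9 ± 2.71 to 18.8 ± 2.88) and the mucin gene Muc3a (36.2 ± 1.68 to 18.9 ± 2.61). Falls were also seen for the semaphorin gene Sema4g (49.2 ± 5.77 to 25.3 ± 3.79) and Sipa1l3 (53.4 ± 13.4 to 24.3 ± 2.77). Plcb2, the phospholipase C of the taste receptor pathway, fell from 8.99 ± 1.97 to 2.84 ± 0.820 CPM, and Grin1, an NMDA receptor subunit gene, from 4.30 ± 2.47 to 0.497 ± 0.190 CPM.

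A further 6 of the genes that rose and 1 of those that fell (Gm38057) had predicted or pseudogene names. Those that rose were Rps10-ps1, Rps10-ps2, Rps15a-ps7, Gm11361, Gm4366 and Gm8730, all named here after their values were seen. Counts of Rps10 and the other ribosomal protein genes are uncertain where reads are shared with such near-identical copies, and exons of Rps10, Rack1, Rps3, Rpl7a, Irgm2 and Grin1 overlap exons of other annotated genes. The count of 26 depended on the scaling and on single libraries. Tcof1 alone was called with DESeq2 size factors or upper-quartile scaling in the same edgeR fit (0 higher, 1 lower), with a correction for transcript length and GC content, or without the 5 most abundant entries. After the length and GC correction the log2 fold changes were 1.14 for Rack1 (1.10 before), 1.16 for Rps10 (1.30), -1.44 for Irgm2 (-1.40) and -1.09 for Muc3a (-0.94), each with an adjusted p of 0.0879 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without wild-type library 3 the edgeR test called 358 genes, without wild-type library 1 or 2 or knockout library 1 or 3 it called 0, and without knockout library 2 it called 1 (Thbs1, named after its value was seen). These 6 fits had 1342 to 3073 genes at an unadjusted p under 0.05, and the DESeq2 Wald test on all libraries called 551 genes.

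**Figure D1:**
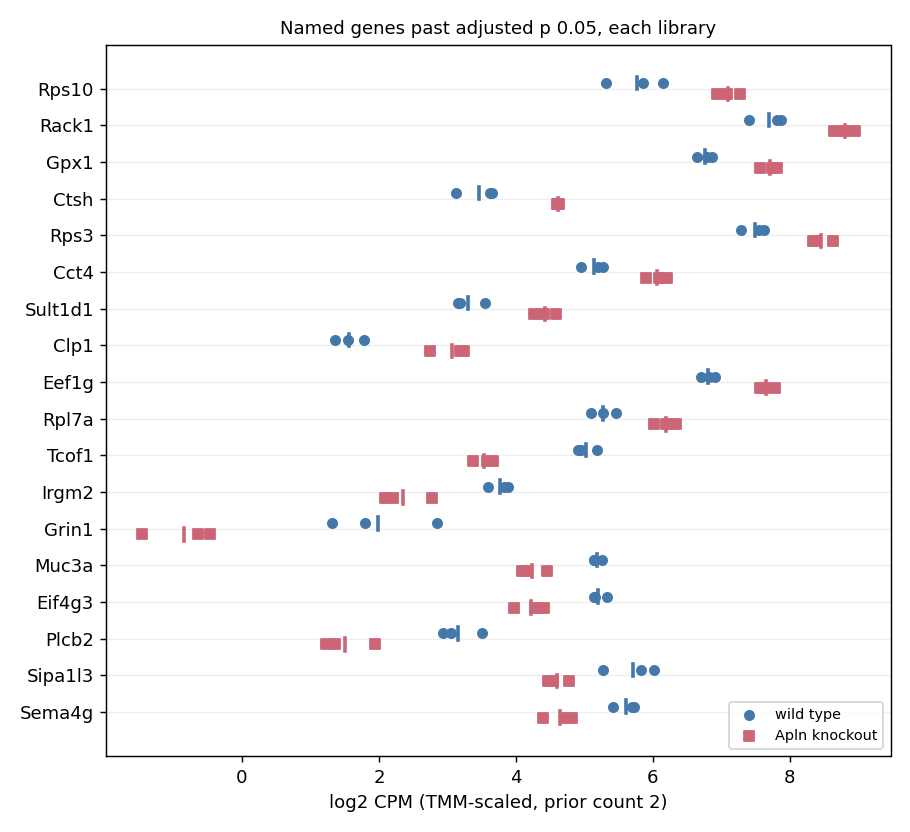
Expression in each library (log2 CPM, horizontal axis) of the 18 genes named here past an adjusted p of 0.05 in edgeR's quasi-likelihood test. Circles are the 3 wild-type and squares the 3 Apln knockout libraries, and vertical bars are group means. For each gene all 3 knockout libraries lie on one side of all 3 wild-type libraries; Rps10 is at 56.1 CPM in wild type and 138 CPM in knockout, and Tcof1 at 32.5 and 11.6 CPM.

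The libraries of the groups also differed in make-up. The 5 most abundant entries (mt-Rnr2, mt-Rnr1, Gm42418, CT010467.1 and Gm23935) took 72.4% ± 2.49 of counts in wild type and 78.0% ± 0.822 in knockout, and mitochondrial ribosomal RNA 52.2% ± 5.29 and 60.2% ± 1.60 (SD, n = 3 each). At an equal depth outside these entries, 20649 ± 511 genes were seen in a wild-type and 22627 ± 389 in a knockout library. Each of these differences separated the 3 knockout from the 3 wild-type libraries, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. Short transcripts were higher and long ones lower in the knockout libraries: the median log2 fold change was 0.25 in the eighth of genes with the shortest transcripts and -0.19 in the eighth with the longest. Over genes, which are not independent replicates, Spearman's rho between fold change and transcript length was -0.26. The knockout libraries were closer to one another (Pearson's r of log2 CPM over genes 0.955 to 0.964) than the wild-type libraries were (0.910 to 0.922). Pairs of a wild-type and a knockout library had 0.915 to 0.941. Wild-type libraries 1 and 3 were each closer to every knockout library than to any other wild-type library.

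**Figure D2:**
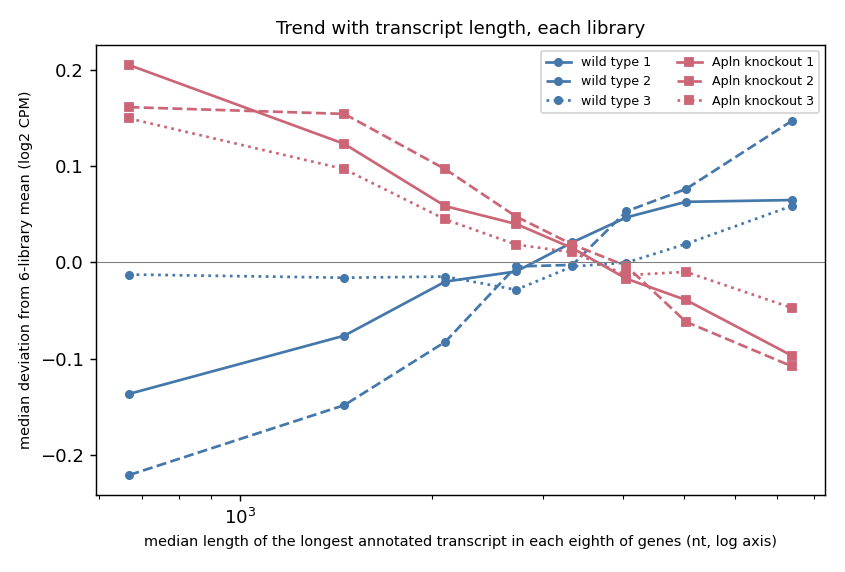
Median deviation of each library from the 6-library mean (log2 CPM, vertical axis) against transcript length (nucleotides, log axis) in eighths of the tested genes. Circles are wild-type and squares Apln knockout libraries, and line styles mark replicates 1 to 3. In the eighth with the shortest transcripts the knockout libraries lie at 0.15 to 0.20 and the wild-type libraries at -0.22 to -0.01.

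Of 35 gene lists tested, 9 passed camera with a preset correlation of 0.01 (adjusted p under 0.05), 7 higher and 2 lower, and 0 passed with a correlation estimated for each list or with fry (2 and 4 lists at an unadjusted p under 0.05). At the preset correlation only, transcripts for cytosolic ribosomal proteins, the respiratory chain and Paneth cells were higher in knockout crypt cells, and those of enteroendocrine and tuft cells were lower. Each list's own value at an estimated correlation is given with it. Markers of stem cells, absorptive enterocytes and goblet cells did not pass as groups with all 6 libraries, but goblet cell genes passed without wild-type library 2 and stem cell genes without knockout library 2.

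Of the 63 measured genes of cytosolic ribosomal proteins, 44 rose and 0 fell when adjusted over the list alone, and 4 rose and 0 fell when adjusted over all genes tested. The median log2 fold change was 0.67 (1.59-fold; quartiles 0.49 and 0.82), with a camera adjusted p of 6.92e-35, and adjusted p = 0.736 with an estimated correlation. The summed level of the list was 3808 ± 559.9 CPM in wild type and 6519 ± 729 CPM in knockout. Rps10, Rps3 and Rpl7a were among those that passed over all genes. A positive log2 fold change was seen for 58 of the 63, and the others, Rpl10a, Rpl10, Rpl15, Rpl30 and Rpl35, named after their values were seen, lay between -0.40 and -0.13. These are short transcripts (median 1120 nucleotides), of the class that was higher in the knockout libraries.

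Nuclear genes of oxidative phosphorylation, which encode subunits of the respiratory chain and ATP synthase, had a median log2 fold change of 0.51 over 45 members (camera adjusted p = 2.79e-15; adjusted p = 0.736 with an estimated correlation). Of these, 22 rose and 0 fell when adjusted over the list alone, and 0 passed when adjusted over all genes. The complex I genes Ndufa9 (22.6 ± 4.70 to 40.7 ± 1.77 CPM, wild type to knockout), Ndufb8 (18.8 ± 4.94 to 34.6 ± 1.95) and Ndufb9 (36.5 ± 6.79 to 60.1 ± 5.76) had the lowest p. They were followed by the ATP synthase gene Atp5o (37.7 ± 7.14 to 60.9 ± 5.51). Their transcripts are also short (median 1363 nucleotides), and the list's median was 0.27 once the trends with length and GC content were taken out of each library. For mitochondrially encoded genes the median was 0.52 over 9 members (camera adjusted p = 3.33e-05; adjusted p = 0.809 with an estimated correlation), and 5 rose when adjusted over the list alone against 0 over all genes. They were mt-Cytb (2839 ± 274 to 5126 ± 1274 CPM), both ribosomal RNAs mt-Rnr1 and mt-Rnr2, mt-Nd5 and mt-Nd1, the last of these named after its value was seen. With the same correction this list's median was 0.12 and its camera adjusted p 0.279, and without knockout library 2 the uncorrected median was 0.31.

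Paneth cells, which secrete lysozyme and defensins at the crypt base, were represented by 20 measured genes with a median log2 fold change of 0.65 (camera adjusted p = 1.69e-05; adjusted p = 0.914 with an estimated correlation). When adjusted over the list alone, 2 rose, Mptx2 (47.5 ± 19.9 CPM in wild type, 117 ± 20.0 in knockout) and the lysozyme gene Lyz1 (468 ± 107 and 1068 ± 476 CPM), and 0 passed when adjusted over all genes. Values of Guca2b (20.3 ± 4.58 and 29.1 ± 1.5 CPM) and the defensin gene Defa3 (1.91 ± 1.07 and 4.43 ± 1.57 CPM) did not pass either test. Defensin genes are near-identical copies of one another, so their separate counts are uncertain. The list's mean deviation per library overlapped between the groups, and its median was 0.42 without knockout library 1 and 1.13 without wild-type library 3.

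Hormone-producing enteroendocrine cells were represented by 27 genes with a median log2 fold change of -0.57 (camera adjusted p = 3.94e-07; adjusted p = 0.603 with an estimated correlation). When adjusted over the list alone 7 fell and 0 rose, and 0 passed when adjusted over all genes. The granule protein genes Chga (94.9 ± 30.4 CPM in wild type, 41.6 ± 7.69 in knockout) and Chgb (567 ± 59.8 and 348 ± 48.9) had the lowest p. Next were the cholecystokinin gene Cck (129 ± 66.7 and 56.9 ± 18.1) and Cryba2 (1.53 ± 0.445 and 0.388 ± 0.252). The summed level of the list was 1633 ± 287 CPM in wild type and 1086 ± 115 CPM in knockout. Tuft cells, chemosensory cells of the epithelium, were represented by 20 genes with a median log2 fold change of -0.86 (camera adjusted p = 7.48e-10; adjusted p = 0.736 with an estimated correlation). Of these, 10 fell and 0 rose when adjusted over the list alone, and 0 passed over all genes. The lowest p belonged to the lipoxygenase gene Alox5 (5.37 ± 1.19 and 1.67 ± 0.769 CPM) and to Pou2f3, the transcription factor that specifies tuft cells (9.53 ± 1.16 and 3.69 ± 1.73). Next were the cation channel gene Trpm5 (19.5 ± 3.46 and 9.70 ± 3.44) and Fyb (17.4 ± 5.71 and 8.14 ± 2.92). Dclk1, the usual tuft cell marker, was at 41.6 ± 8.65 and 20.7 ± 8.44 CPM. The mean deviation of the tuft list overlapped between the groups, and that of the enteroendocrine list did not. The summed level of the tuft list, 62.0% of it from Cd24a, did not overlap (409 ± 19.5 CPM in wild type, 286 ± 69.0 in knockout).

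The other lists that passed were smaller in size of effect. Fatty acid oxidation and PPAR genes had a median log2 fold change of 0.32 over 25 members (camera adjusted p = 0.0153; adjusted p = 0.809 with an estimated correlation). Of these 0 passed, either adjusted over the list alone or over all genes. Ech1 (12.7 ± 3.76 CPM in wild type, 21.4 ± 1.52 in knockout), Eci1 (6.91 ± 2.81 and 11.6 ± 0.988) and Acaa2 (log2 fold change 0.52) were among those of lowest p. So was Fabp1, a fatty acid binding protein gene with the opposite sign (5.69 ± 2.16 and 2.83 ± 0.700). Immediate early and heat shock genes, which respond to cell handling, had a median of 0.25 over 24 members (camera adjusted p = 0.0254; adjusted p = 0.999 with an estimated correlation). Again 0 passed when adjusted over the list alone or over all genes. Antioxidant and NRF2 target genes had a median of 0.17 over 19 members (camera adjusted p = 0.0254; adjusted p = 0.736 with an estimated correlation). When adjusted over the list alone 3 of them rose, Gpx1, Gsta4 (1.90 ± 0.715 and 4.85 ± 1.46 CPM) and Prdx1 (116 ± 5.18 and 171 ± 26.3 CPM), and 1, Gpx1, when adjusted over all genes. Single libraries decided these calls. Fatty acid oxidation had a camera adjusted p of 0.308 without wild-type library 1 (median 0.16) and 0.0543 without knockout library 3, and a median of 0.21 without knockout library 2. Immediate early genes had an adjusted p of 0.684 without wild-type library 1 (median 0.15), 0.107 without knockout library 1 and 0.647 without knockout library 3 (median 0.12), and a median of 0.47 without knockout library 2. Antioxidant genes had an adjusted p of 0.205 without wild-type library 1 and 0.0994 without knockout library 2, and a median of 0.29 without wild-type library 3. The antioxidant list had a median of 0.07 and a camera adjusted p of 0.0921 after the length and GC correction.

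**Figure D3:**
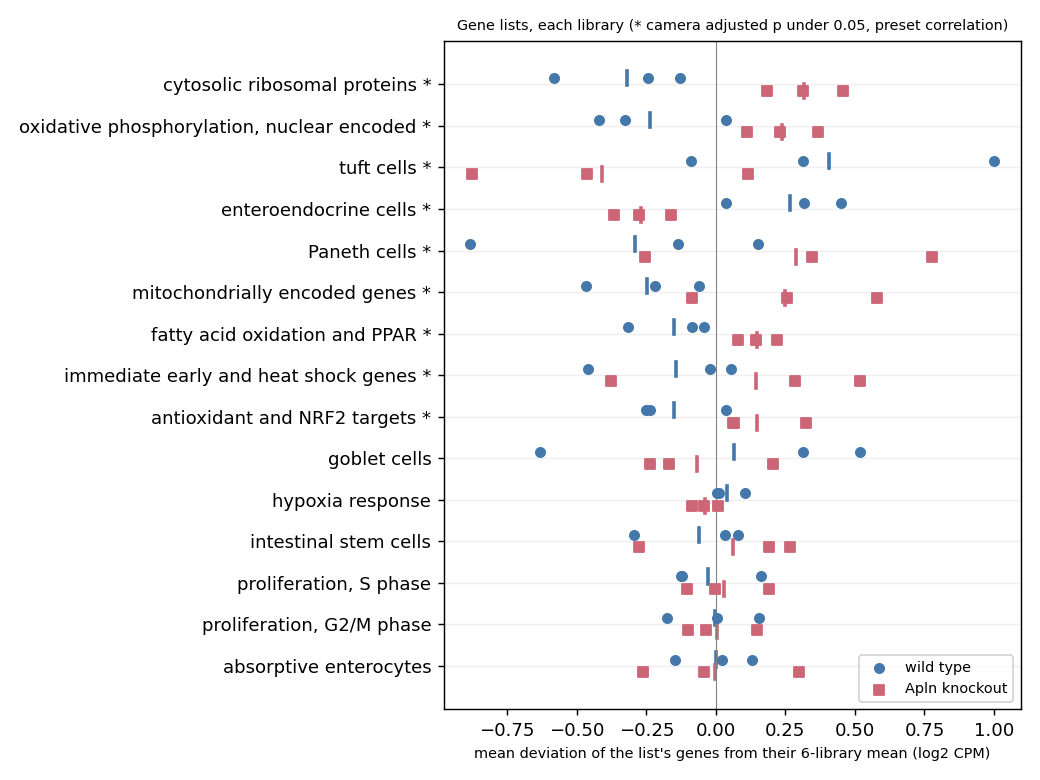
Mean deviation of each list's genes from their 6-library mean (log2 CPM, horizontal axis) in each library, for the 9 lists past a camera adjusted p of 0.05 with a preset correlation (asterisks) and 6 others. Circles are wild-type and squares Apln knockout libraries, and vertical bars are group means. The groups separate for ribosomal proteins, oxidative phosphorylation, enteroendocrine cells, fatty acid oxidation and antioxidant genes, and overlap for tuft and Paneth cells.

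Intestinal stem cell genes had a median log2 fold change of -0.00 over 25 members (mean 0.10), with 0 passing when adjusted over the list alone or over all genes. The list's camera adjusted p was 0.843 with all libraries and 0.0320 without knockout library 2, where the median was 0.15. Lgr5 was at 33.0 ± 6.06 CPM in wild type and 33.0 ± 6.64 in knockout, and Olfm4 at 716 ± 169 and 875 ± 301. Wnt pathway genes (median -0.02 over 25), S phase genes (0.07 over 24) and p53 targets (0.11 over 18) did not pass either. Nor did secretory progenitor and Notch genes (-0.11 over 15) or cholesterol biosynthesis genes (-0.05 over 22). In each of these lists 0 members were called when adjusted over the list alone or over all genes. Of 25 G2/M phase genes (median 0.05), Mki67 fell and Aurka rose when adjusted over the list alone, and 0 passed over all genes. Mki67, the common proliferation marker, was at 355 ± 46.0 and 201 ± 32.9 CPM, and Aurka at 8.61 ± 1.83 and 14.2 ± 0.415. The longest annotated transcripts have 10061 nucleotides for Mki67 and 1905 for Aurka. Long transcripts as a class were lower in the knockout libraries.

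Goblet cell genes (median -0.18 over 22), absorptive enterocyte genes (0.08 over 28), upper villus genes (-0.04 over 15) and genes of the proximal small intestine (0.19 over 15) had 0 members called when adjusted over the list alone or over all genes. The goblet result hung on single libraries: without wild-type library 2 its median was -0.46 with a camera adjusted p of 5.68e-06, and without wild-type library 1 they were 0.01 and 0.936 (0.372 with all). The mucin gene Muc2 was at 1044 ± 746 and 512 ± 85.8 CPM, a difference within the wild-type spread, and the enterocyte gene Alpi at 16.5 ± 3.84 and 14.5 ± 2.01. Hypoxia response genes (median -0.17 over 28), glycolysis genes (0.21 over 20) and MHC class II genes (-0.25 over 8) also had 0 called by either adjustment. The hypoxia median was -0.07 without knockout library 3, and the glycolysis median 0.09 without wild-type library 1. When adjusted over the list alone, with 0 over all genes, single genes passed in several further lists. Mptx2 rose among distal small intestine genes (median 0.07 over 20), Ccl25 among lower villus antimicrobial genes (0.05 over 15), and Cldn7 among the epithelial sort markers (0.11 over 8). Without knockout library 2 the lower villus list passed camera (median -0.26, adjusted p = 0.00624), as did the epithelial sort markers without wild-type library 3 (0.23, adjusted p = 0.0118). Ern2 fell among genes of the unfolded protein response (0.04 over 26). Among angiogenic factors (median -0.11 over 15) Ccl25 (86.8 ± 10.5 and 152 ± 9.48 CPM) and Edn1 (3.67 ± 2.34 and 14.2 ± 7.69) rose on that count, and among YAP targets (0.12 over 13) Ccn1 rose and Sprr1a fell. The interferon response list had a median of -0.22 over 30 members and a camera adjusted p of 0.0730 (adjusted p = 0.931 with an estimated correlation). Igtp and Iigp1 fell when adjusted over the list alone, and 0 passed over all genes. Exons of Igtp overlap those of Irgm2 on the same strand, so the falls of Igtp and Irgm2 may not be independent. Irgm2 is not a member of this list. With the length and GC correction this list passed camera, with a median of -0.32 and an adjusted p of 0.0269 (adjusted p = 0.952 with an estimated correlation). Uncorrected, it passed without wild-type library 1 (0.0357), wild-type library 2 (0.00675) or knockout library 3 (0.0260, median -0.38), and without wild-type library 3 its median was -0.02 and its camera adjusted p 0.644. Median, mean or test differed in sign for the lists of stem cells, enterocytes, G2/M phase, upper villus, lower villus, distal small intestine, cholesterol biosynthesis, unfolded protein response, YAP targets, angiogenic factors, myeloid cells and fibroblasts, none of which passed camera with all libraries. All lists in this paragraph and the last had camera adjusted p values of 0.0730 to 0.999 with all libraries. Of the 26 lists that did not pass, 19 had a median of the other sign without 1 of the libraries, and in 25, all but MHC class II, leaving out 1 library moved the median by more than 1.5 times.

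None of the lists for cells outside the sort gate passed camera or had separate groups in its summed level. Single members did separate the groups, Ptprc among those lower in knockout and Acta2 among those higher. Summed levels were 7.93 ± 3.42 CPM in wild type and 6.48 ± 1.07 CPM in knockout for T cells and intraepithelial lymphocytes, and 26.6 ± 6.06 and 22.0 ± 2.48 for myeloid cells. They were 34.5 ± 24.1 and 32.2 ± 18.4 for fibroblasts and smooth muscle and 199 ± 157 and 131 ± 81.7 for B and plasma cells (n = 3 each). The B and plasma cell genes, with 47.2% of their sum from the immunoglobulin gene Igha, were at 282 and 297 CPM in wild-type libraries 1 and 2, near the level of Epcam, and at 17.3 CPM in library 3. Fibroblast and smooth muscle genes were likewise lowest there (6.75 CPM). These lists had median log2 fold changes of -0.12, 0.05, -0.52 and 0.00, with 0 members called when adjusted over the list alone or over all genes, and the 5 sex check genes had a median of 0.05 and likewise 0 called. Single libraries turned the sign of these medians: 0.27 without knockout library 3 and -0.70 without knockout library 2 for T cells, and 0.21 without wild-type library 1 and -0.36 without wild-type library 3 for myeloid cells. They were 0.11 and -0.84 for fibroblasts and smooth muscle without the same libraries, and 0.80 without wild-type library 1 and -0.66 without knockout library 1 for B and plasma cells. Endothelial, enteric glia and erythroid lists had fewer than 5 measured genes and were not tested. Their summed levels were 17.2 ± 3.34 and 12.6 ± 3.12, 1.63 ± 0.698 and 2.18 ± 0.915, and 1.12 ± 0.544 and 0.781 ± 0.198 CPM (exact permutation p of 0.3, 0.6 and 0.5, two-sided, n = 3 each). Prox1 gave 59.3% of the endothelial sum, Ret 63.1% of the glia sum and Alas2 50% of the erythroid sum, so each rests largely on 1 gene.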

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

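The length and GC correction and the fit without the 5 most abundant entries were chosen after the data had been seen; the other alternatives were planned. The count of 26 changed genes moved with nearly every choice. In edgeR it was 1 (Tcof1) with DESeq2 size factors, with upper-quartile scaling, with the length and GC correction and without the 5 most abundant entries. It was 0 with a fold minimum of 1.5 (529 genes at an unadjusted p under 0.05; the DESeq2 Wald test called 551 with no minimum). With both other scalings the log2 fold changes of the other genes hardly moved, for example 1.08 and 1.11 for Rack1 against 1.10. Its adjusted p was 0.0501 and 0.0531 against 0.0460 (5.94e-08 to 0.765 over all alternatives), so those calls lay just at the threshold. The count was 56 with limma-voom (43 higher, 13 lower), 204 with quality weights (146 and 58) and 86 with a robust fit (59 and 27). It was 117 with a minimum of 1 CPM (83 and 34), 551 with the DESeq2 Wald test (264 and 287) and 629 with no filter (328 and 301). All 26 genes were among the calls of each of these but limma-voom, which shared 25. Leaving out 1 library gave 0 to 358 genes, 358 without wild-type library 3 and 0 or 1 without any other; the cause was not tested. The replicate block gave 173 genes (118 higher, 55 lower) and 9 lists. Samples of the same number had weakly positive correlations of deviations (0.0406, 0.0569 and 0.0109), and other pairs had -0.0518 to 0.0169. Deviations were taken from each group's own mean, so positive values for some pairs force negative ones for others. The contrast between these sets of pairs is therefore not separate evidence. Not every library correlated best with its own number: knockout library 3 did so with wild-type library 1 (0.0169). Numbers here follow the sample titles, and the deposited column labels number the knockout samples otherwise, so a pairing by those labels was not tested. This check is a hint from the data and not part of the design. The 9 lists were 9, 10, 8 and 9 with DESeq2 size factors, the 1 CPM minimum, the length and GC correction and without the 5 entries, and 7 to 11 without 1 library. These were not always the same lists: 7 of the 8 after the length and GC correction were among the original 9. Without 1 library, 6 (wild-type library 1) to 9 (wild-type library 2 or 3) of the original 9 passed. With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05) and with fry 0 (4). Estimated correlations of the 9 lists ran from 0.0559 (antioxidant genes) to 0.822 (mitochondrially encoded genes), and a higher one widens a list's error more. Wild-type Apln was 0.199 to 0.670 CPM without 1 library, lowest without wild-type library 1. Over all alternatives, called named genes kept their direction and passed in 155 cases and kept it without passing in 187; called lists did so in 90 and 27. Among 2775 cases of genes and lists not called, 65 changed sign, Lgr5 in 9 of them. Depth limits genes such as Apln, Aplnr and Pecam1, which fell under the count filter.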

Other observations

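The tests of the length and GC trend and of pseudogenes were chosen after the data had been seen. Leaving out each library was planned, but its use as a test on the enteroendocrine and tuft lists, with its bound, was chosen after. The bounds for the trend were set before any corrected value was seen, and those for genes near Apln and for other splits of the samples before their values were seen. A few genes, picked here after their values were seen, missed the threshold of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment by little. They were the class I gene H2-K1 (172 ± 6.06 CPM in wild type and 105 ± 5.39 in knockout, SD, n = 3 each; adjusted p 0.0546), the tight junction gene Cldn8 (0.515 ± 0.319 and 3.61 ± 1.00 CPM; 0.0504) and Plet1 (8.74 ± 7.93 and 1.15 ± 0.263 CPM; 0.0517).

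In camera at a preset correlation only, cytosolic ribosomal protein and respiratory chain genes were higher in knockout, and both lists hold short transcripts. When adjusted over the list alone 44 of 63 and 22 of 45 members rose, and 4 and 0 over all genes. With the trends in length and GC content taken out of each library, the medians were 0.47 and 0.27 (0.67 and 0.51 before) and both lists still passed camera at a preset correlation. At an estimated correlation they did not pass, before (adjusted p = 0.736 for both) or after (0.704 and 0.952). Without each library in turn the corrected medians were 0.37 to 0.56 and 0.20 to 0.44. The correction used each gene's longest annotated transcript, 3183 nucleotides for Rps3 for example, which need not be the one expressed. Part of the trends may therefore remain in the corrected medians, which cannot decide whether the trends are the whole cause. Reads moved from ribosomal protein pseudogenes to their parents would lower the pseudogenes, yet 48 of 50 measured ones had a positive log2 fold change, with a median of 0.75. Such copies share reads with their parents, so their rise may come from reads of the parents and is not separate evidence. The knockout genotype may raise these transcripts, and a difference in RNA quality, amplification or cell handling between the groups, untested beyond the trend, stays open beside it, since the share of ribosomal RNA and the number of genes seen separate the same libraries.

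In camera at a preset correlation only, enteroendocrine and tuft cell genes were lower in knockout, and the tuft list's mean deviation overlapped between the groups. When adjusted over the list alone 7 of 27 and 10 of 20 members fell, and 0 over all genes. The length and GC trend does not account for all of it, since the medians after correction were -0.67 and -0.89 (-0.57 and -0.86 before). At an estimated correlation the lists did not pass camera before (adjusted p = 0.603 and 0.736) or after the correction (0.461 and 0.704). No single library set it: without each library in turn the medians stayed at or below -0.45 (without wild-type library 2) and -0.67 (without knockout library 2). Fewer of these cells among those sorted, lower expression within them and a sort gate that took a different share are all candidate explanations. Bulk counts do not separate them. A difference in RNA quality, amplification or cell handling between the groups stays open here as well, since library make-up separates the same libraries.

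A knockout allele may carry a flanking segment of the strain it was made in. Of 41 tested genes within 10 Mb of Apln on the X chromosome, 9 (22.0%) had an unadjusted p under 0.05, against 15.2% of the 15075 genes elsewhere. The odds ratio was 1.57 (95% interval 0.659 to 3.38; Fisher's exact test, two-sided, p = 0.271), and 0 of the 41 passed the adjusted threshold of edgeR's test. The interval holds both no enrichment and a marked one, so the hypothesis stays open. The allele's strain of origin is not given in the sources used here, and differences in background farther from Apln were not tested.

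The real split of the 6 libraries called 26 genes, the highest of the other 9 splits 0 (2297 and at most 912 genes at an unadjusted p under 0.05), so 1 of 10 splits gave as many. For lists at the preset correlation, 8 of 10 splits gave as many as the real 9, and the highest of the others gave 16. For genes, a share under 0.05 cannot be reached with 10 splits. For lists the real split did not stand out, since most splits of mixed genotype called as many lists or more. The largest median of all 10 splits, in absolute size, fell to the real split for ribosomal proteins (0.67, highest other 0.44), the respiratory chain (0.51 and 0.41), enteroendocrine cells (0.57 and 0.41), tuft cells (0.86 and 0.83) and fatty acid oxidation (0.32 and 0.23). It also did for lists that did not pass camera, hypoxia response (0.17 and 0.13), glycolysis (0.21 and 0.19) and MHC class II (0.25 and 0.21), so it does not set the lists that passed apart. It did not for Paneth cells (3 splits as large), mitochondrially encoded genes (2), immediate early genes (5) or antioxidant genes (5).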
